A study of Mus musculus with 24 samples.

How the data were processed

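Messenger RNA of isolated mouse brain vessels was measured in 24 libraries, 6 for each combination of genotype (APP/PS1 or WT) and sex. Per the labels' protocols, total RNA was extracted with a column kit, 200 ng entered a poly(A)-selecting TruSeq library preparation, and the libraries were sequenced on a NextSeq 2000. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here, so overlapping genes, antisense genes and near-identical gene copies could share reads.

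The deposited table holds CPM (read counts scaled to the library's total), a unit read from its column names, which end in norm, and from its values. In every column all values were whole multiples of a single step, within a tolerance of 0.01 reads, for 100% of values. The step gave each library's total of 52.39 to 75.93 M reads, with a median of 65.51 M. Between 99.331% and 99.447% of that total lay in the listed genes. The values therefore carried no scaling between libraries other than the total. The table had 15346 rows, of which 1598 had no value in any library. Of the other 13748, 10 repeated rows of 2 symbols were removed, which left 13738 genes. The lowest mean of a tested gene was 0.886 CPM, and every tested gene had at least 1 CPM in at least 6 libraries. The deposited table thus held no values of lower genes, as a filter on low genes before deposit would leave it. A count of 0 allows up to 3 reads, which is 0.0395 to 0.0573 CPM depending on the library; this covers counting error only. At these totals, sampling error was small beside the spread between mice for most genes, whose median level was 25.6 CPM.

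Groups came from the genotype, sex and replicate number in the titles. The design states 6 mice per sex and genotype, so p-values measure the spread between mice. All values were analysed as log2(CPM + 1), and fold changes are on that scale, which understates changes of genes with low values. A linear model with the 4 group means was fitted to all 24 libraries with limma version 3.58.1 in R version 4.3.3, with a mean-dependent prior (limma-trend). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A count test had been chosen first on the assumption of raw counts, with limma-trend on the log scale as the stated fallback; since the deposited unit was CPM, the fallback was used, and count tests on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0) served as alternatives. Of 791 members of 50 gene lists, fixed before the data were examined, 726 were measured. The 47 lists with at least 5 measured genes that were not label checks were tested with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. Camera for the sex comparison was added after seeing the data.

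Named genes followed a rule set before the data were examined. They were the label checks, the 10 largest rises and 10 largest falls of the main comparison and the 5 of each in the others (mean of at least 1 CPM, called, no numbered gene models), and up to 4 members with the smallest p of each list discussed; which lists are discussed was chosen after the results were seen. Some genes that the rule names are not reported here, though lists and counts of all genes include them. Genes named for library-name style or for the long-named females were chosen after their values were seen. Gene positions came from the GENCODE annotation of the same build, which placed 13582 of the genes. Alternatives covered scaling, pseudocount, low-value filter, threshold, count tests, covariates, surrogate variables (sva 3.50.0), library-name style, a replicate block and leaving out each library. The script was tested on simulated counts of the 13738 genes. For the comparison averaged over sexes it recovered 68% of genes changed by 0.5 log2 units and 91% of those changed by 1, and 2.5% of its calls were unchanged genes. For the interaction it recovered 18% and 64%. Simulated genes were independent, unlike real ones.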

Results

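Brain vessels were profiled from APP/PS1 mice (APP below), a transgenic line that models familial Alzheimer's disease and deposits amyloid plaques, and from WT mice. The vessels had been captured with magnetic beads against CD31, a surface protein of endothelial cells. The mice were 9 to 11 months old. The 4 groups of 6 mice were APP males, APP females, WT males and WT females. Recovered library totals averaged 63.69 ± 3.94 M reads in APP males, 66.02 ± 7.38 in APP females, 60.22 ± 5.95 in WT males and 65.01 ± 6.59 in WT females (SD, n = 6 each). Values are CPM, and 13738 genes were tested.

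The sex labels matched the sex-linked genes. Xist, the RNA that silences the X chromosome, was at 389 ± 52.9 CPM in APP females and 399 ± 63.4 in WT females, against 0.31 ± 0.256 and 0.387 ± 0.51 in APP and WT males (SD, n = 6). Ddx3y, a Y-linked gene, was at 189 ± 16.2 CPM in APP males and 179 ± 31.4 in WT males, and at 0.101 ± 0.102 and 0.174 ± 0.132 in the females; Kdm5d, Eif2s3y and Uty did likewise. The counts of App did not separate the genotypes (2420 ± 283 CPM in APP, 2460 ± 306 in WT, n = 12; log2 fold change -0.02, SE 0.07, adjusted p = 0.89). Nor did those of Prnp (0.01, SE 0.08, adjusted p = 0.98), so these genes give no check of the genotype labels.

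Libraries carried names of 2 styles, a short one (a letter with 1 or 2 digits) and a long one (a letter with 4 digits). Short names belonged to 4 APP males, 4 APP females and all 6 WT males, and long names to 2 APP males, 2 APP females and all 6 WT females. Within APP, 425 genes were higher and 914 lower in short-named libraries, with the sexes averaged. Pttg1, which encodes securin (chromosome 11, 43420250 to 43426251, mm10), was at 3.25 to 5.12 CPM in the short-named APP libraries and at 55.9 to 62.7 in the long-named ones. WT males had 25.2 to 35.4 CPM and WT females 48.7 to 67.6. Manba, a lysosomal mannosidase (chromosome 3, 135485611 to 135571404), was at 25.2 to 33 and 69.7 to 73.2 CPM in the same APP sets, at 37.3 to 45.6 in WT males and at 66.8 to 80.6 in WT females. Hpgd, which degrades prostaglandins, was also lower in the short-named APP libraries, at 1.41 to 3.33 against 17.8 to 42.3 CPM. Ifi44l, an interferon-inducible gene, was higher in them, at 3.67 to 26.4 against 0 to 0.0178 CPM. The style therefore divides the APP groups and coincides with sex in WT. Values within 1 style are given for males and for females, and the other comparisons mix the styles. The females with long names, 2 APP and 6 WT, are the only set that compares the genotypes within 1 style of name without the WT males.

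**Figure D1:**
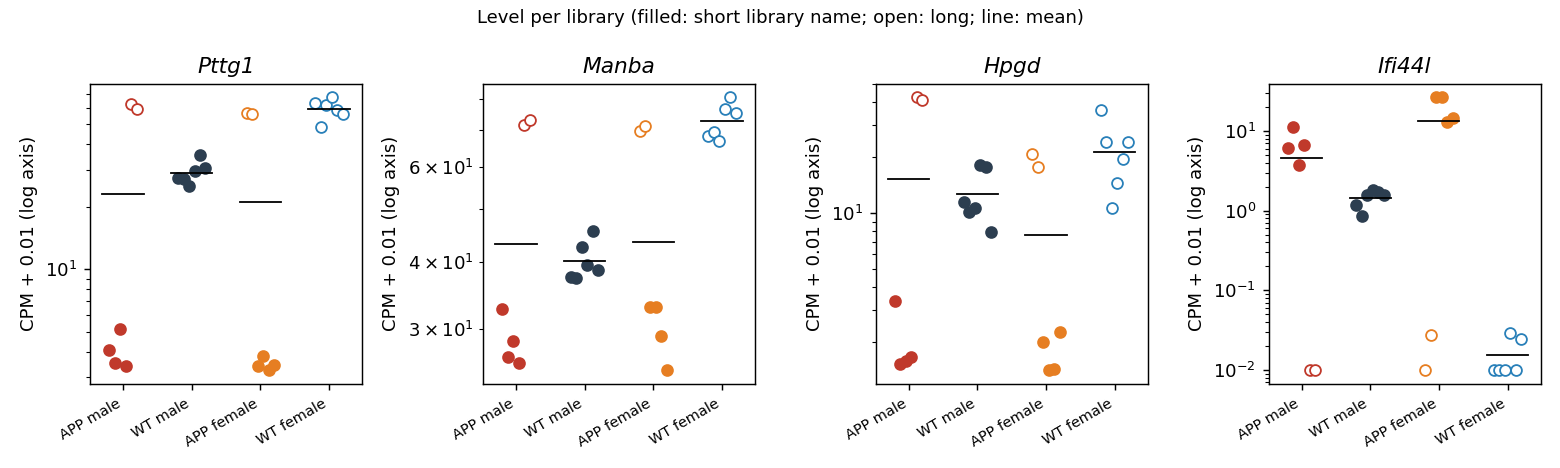
Levels of Pttg1, Manba, Hpgd and Ifi44l per library, as CPM + 0.01 on a log axis, for the 4 groups of 6 mice. Filled points are short-named libraries, open points long-named ones and lines group means; the short-named APP libraries lay at 3.25 to 5.12 CPM of Pttg1 and the long-named ones at 55.9 to 62.7.

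APP was first compared with WT with the sexes averaged, which asks how vessels with amyloid pathology differ from those without. The largest rises were genes that microglia switch on around plaques. Cst7, a lysosomal protease inhibitor (chromosome 2, 150570415 to 150578944), was at 80.4 ± 42.3 CPM in APP and 1.87 ± 2.34 in WT (SD, n = 12; log2 fold change 4.85, SE 0.34, adjusted p = 2e-09). Clec7a, the receptor dectin (29.1 ± 13.5 against 1.47 ± 0.87 CPM), rose by 3.53 (SE 0.25), and Itgax, the integrin CD11c (47.4 ± 21.3 against 4.11 ± 1.41 CPM), by 3.15 (SE 0.22). In each of the 3, every APP library was above every WT library. All 23 measured genes of the plaque-associated microglia list rose, and 23 did when adjusted over the list alone (median log2 fold change 0.95; camera adjusted p = 6.1e-33; adjusted p = 0.049 with an estimated correlation). Homeostatic microglia markers did not move together (0 of 13 called, median 0.08, adjusted p = 0.34).

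Inflammatory signals rose with them. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), was at 18.7 ± 11.3 CPM in APP and 0.981 ± 0.504 in WT (log2 fold change 3.14, SE 0.26, adjusted p = 4.1e-08). The cytokine gene Il1b rose by 2.43 (SE 0.23), the chemokine gene Cxcl10 by 2.29 (SE 0.23), the checkpoint receptor gene Pdcd1 by 2.07 (SE 0.19), Spp1, which encodes osteopontin, by 2.01 (SE 0.21), the growth factor gene Igf1 by 1.9 (SE 0.28) and the oxygen-sensing hydroxylase gene Egln3 by 1.89 (SE 0.18). Of 15 leukocyte adhesion and chemokine genes 9 rose and 1 fell, or 10 and 2 when adjusted over the list alone; Cxcl16 rose by 1.25 (SE 0.16) and Tnf by 1.62 (SE 0.2). That list had a median of 0.49 (adjusted p = 4.5e-07; adjusted p = 0.079 with an estimated correlation). Among 25 interferon response genes 7 rose, and 11 when adjusted over the list alone, led by Isg15 (0.72, SE 0.11), Ifit2 (1.03, SE 0.17), Ifi44 (0.89, SE 0.16) and Mx1 (0.84, SE 0.15). Its median was 0.19 (adjusted p = 8.6e-06; adjusted p = 0.64 with an estimated correlation).

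**Figure D2:**
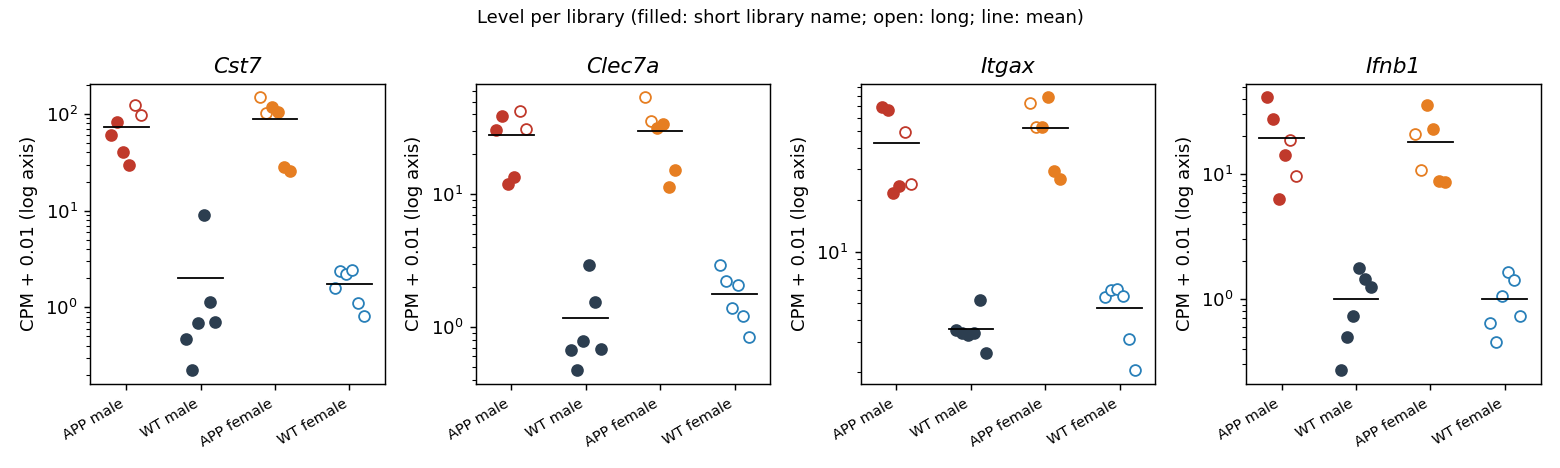
Levels of Cst7, Clec7a, Itgax and Ifnb1 per library, as CPM + 0.01 on a log axis, for the 4 groups of 6 mice. Filled points are short-named libraries, open points long-named ones and lines group means; Ifnb1 lay at 6.27 to 41 CPM in APP and at 0.26 to 1.75 in WT.

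Contractile genes of vascular smooth muscle fell. Of 14 measured, 12 fell, and 13 did when adjusted over the list alone (median -0.64; adjusted p = 1e-08; adjusted p = 0.34 with an estimated correlation). Des, which encodes desmin, was at 29.4 ± 8.88 CPM in APP and 52 ± 15.1 in WT (log2 fold change -0.8, SE 0.16, adjusted p = 0.0028); Smtn (-0.49, SE 0.08), Lmod1 (-0.89, SE 0.19) and Mylk (-0.45, SE 0.1) fell too. Glucocorticoid-responsive genes formed another falling group, with 12 of 15 lower and 1 higher, the same counts as when adjusted over the list alone (median -0.65; adjusted p = 2.5e-06; adjusted p = 0.13 with an estimated correlation). Fkbp5, a chaperone that restrains the glucocorticoid receptor, was at 38.9 ± 25.9 CPM in APP and 96.8 ± 60.8 in WT (-1.27, SE 0.23, adjusted p = 0.0011). Cdkn1a (-0.78, SE 0.14), Plin4 (-0.88, SE 0.19) and Mt2 (-0.65, SE 0.14) were lower as well. Of the astrocyte markers 5 of 13 fell and 1 rose (median -0.54; adjusted p = 0.013; adjusted p = 0.64 with an estimated correlation). The fall lay in the short-named APP males, whose mean of centred log2(CPM + 1) over the list was -1.24 to -0.91. The long-named APP males had 0.56 and -0.19, and WT males 0.11 to 1.09. In females that mean was not lower in APP (0.21 ± 0.56) than in WT (-0.03 ± 0.4, SD, n = 6 each).

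Among the largest single falls were Rpl21 (-2.34, SE 0.44), Pttg1 (-1.95, SE 0.51), the amino acid oxidase gene Lao1 (-1.93, SE 0.21), the kinase gene Map3k6 (-1.76, SE 0.32), the glycosyltransferase gene B3gnt3 (-1.59, SE 0.36), the thyroid hormone deiodinase gene Dio2 (-1.57, SE 0.3), Hif3a of the hypoxia-inducible family (-1.4, SE 0.2), the iron-siderophore carrier gene Lcn2 (-1.36, SE 0.38) and the GABA transporter gene Slc6a11 (-1.35, SE 0.33). Rpl21 has near-identical copies and is uncertain. Pttg1 and B3gnt3 were low in the short-named APP libraries, B3gnt3 at 2.92 to 6.4 CPM against 22.2 to 38.5 in the long-named ones. Among 19 blood-brain barrier transporters, 4 rose and 1 fell, or 4 and 2 when adjusted over the list alone, with no call for the list (median 0.04, adjusted p = 0.17). The transferrin receptor gene Tfrc rose by 0.89 (SE 0.17), Slc16a1 by 0.95 (SE 0.21) and Slc7a1 by 0.38 (SE 0.09), while Slc2a1, which encodes the glucose transporter of the barrier, fell from 4720 ± 741 CPM in WT to 3550 ± 916 in APP (-0.44, SE 0.1, adjusted p = 0.0073). Tfrc and Slc2a1 were called within females (1.38, SE 0.23 and -0.67, SE 0.15) but not within males. The difference between the sexes was not called for either (0.99, SE 0.33 and -0.46, SE 0.21). The rise of Slc16a1 lay in the short-named APP libraries (930 to 1650 CPM); the long-named ones had 360 to 546 CPM, WT males 428 to 488 and WT females 293 to 457.

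In this comparison 657 genes were higher and 1006 lower, and the median of all genes was -0.007. Without the 4 short-named APP males the counts were 437 and 309, without the 4 short-named APP females 192 and 252, and with a score of clock genes as a covariate 123 and 66. All 3 were chosen after seeing the data, and in the first the males differ in name style as well as genotype. In males the clock score went largely with genotype, at -0.69 to 1.88 in APP and -1.63 to -0.51 in WT. As a covariate it therefore also takes up differences of genotype. Of the 47 lists 13 were called up and 4 down, but 33 of 100 splits of the libraries with genotype shuffled within sex, the real one included, called at least as many, so the number of list calls was not beyond chance. List by list, splits with a camera p as small as the real one numbered 1 of 100 for plaque-associated microglia and 2 for leukocyte adhesion and chemokines. They numbered 4 for smooth muscle, but 5 within males and 9 within females. For glucocorticoid response they numbered 5, for interferon response 30 and for astrocyte markers 24. At least 5 of 100 was taken as within chance, so these lists were not beyond it. The split numbers were not corrected for testing 47 lists. The calls of Pttg1 ended with edgeR (adjusted p = 0.29) and DESeq2 (adjusted p = 0.25) on the recovered reads, and those of B3gnt3 and Slc6a11 with edgeR (adjusted p = 0.057 and 0.063).

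The same question was asked in males. The plaque-associated genes led the rises again: Cst7 rose by 4.92 (SE 0.48), Clec7a by 3.68 (SE 0.35), Ifnb1 by 3.19 (SE 0.36), Itgax by 3.12 (SE 0.31) and Cxcl10 by 2.69 (SE 0.32). Of the 23 microglial genes 18 rose (median 1.18; adjusted p = 5e-21; adjusted p = 0.11 with an estimated correlation), and 20 did when adjusted over the list alone. The largest falls were Crym, which encodes a thyroid hormone-binding protein (0.488 ± 0.541 CPM in APP males, 11.6 ± 1.87 in WT males; -3.14, SE 0.52, adjusted p = 0.00069), Dio2 (-2.69, SE 0.43), Rpl21 (-2.49, SE 0.62), the glial glutamate transporter gene Slc1a2 (-2.36, SE 0.48) and the neuronal kinesin gene Kif5a (-2.3, SE 0.74).

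Markers of cells that surround the vessels were lower in APP males, mainly in the short-named ones. Astrocyte markers fell in 9 of 13, and in 10 when adjusted over the list alone (median -1.28; adjusted p = 7.8e-06; adjusted p = 0.35 with an estimated correlation), with Slc4a4 at -1.46 (SE 0.32), Mlc1 at -1.96 (SE 0.45) and Aldoc at -2.1 (SE 0.49). Pericyte markers fell in 5 of 14, or 7 when adjusted over the list alone: Notch3 (-0.84, SE 0.2), Rgs5 (-0.76, SE 0.21), Zic1 (-0.85, SE 0.23) and Pdgfrb (-0.76, SE 0.22). The pericyte median was -0.63 (adjusted p = 8.4e-05; adjusted p = 0.5 with an estimated correlation). Clock genes moved in both directions, with 6 of 15 higher and 2 lower, or 8 and 2 when adjusted over the list alone (median 0.63; adjusted p = 0.0018; adjusted p = 0.21 with an estimated correlation). Dbp rose from 5.49 ± 1.82 to 46.5 ± 33.2 CPM (2.52, SE 0.43), Nr1d2 by 1.28 (SE 0.17) and Per3 by 0.9 (SE 0.14), while Npas2, which is expressed in antiphase to them, fell from 21.6 ± 2.53 to 7.83 ± 3.69 CPM (-1.44, SE 0.2).

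In males 704 genes were higher and 1262 lower. Voom and DESeq2 on the recovered reads called more genes higher, so the balance rests in part on the scaling and test. With only the 4 short-named APP males against WT males 755 genes were higher and 2116 lower. Without them the balance turned to 611 higher and 256 lower. That fit sets long-named APP males against short-named WT males, so it cannot part genotype from name style. With the clock score as a covariate 69 were higher and 68 lower. Since that score went largely with genotype in males, this drop does not part the clock from genotype. Without APP male replicate 2, 828 genes were lower. The call of Kif5a ended when any of APP male replicates 1 to 4 or WT male replicates 3 to 6 was left out (adjusted p = 0.051 to 0.098), and without APP males 1 to 4 the median of the pericyte list was 0.05 and that of the clock list 0.13, neither called. With genotype shuffled, a camera p as small came in 1 of 100 splits for plaque-associated microglia. It came in 5 for astrocyte markers, 20 for pericyte markers and 18 for clock genes, so these lists were not beyond chance.

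**Figure D3:**
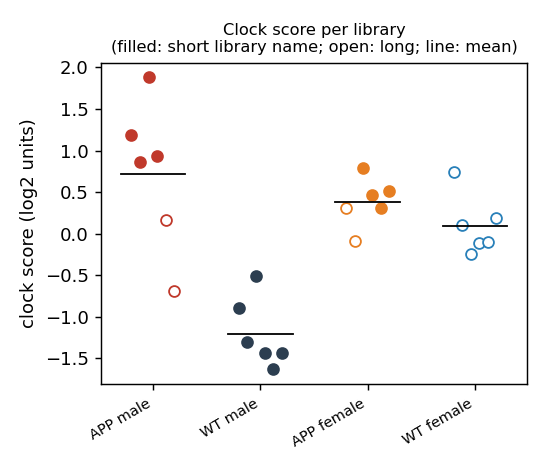
Clock score per library, the mean of centred log2(CPM + 1) of genes such as Dbp minus that of genes in antiphase such as Npas2, in log2 units, for the 4 groups of 6 mice. Filled points are short-named libraries, open points long-named ones and lines group means; the 4 short-named APP males lay at 0.86 to 1.88 and WT males at -1.63 to -0.51.

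In females the rises were led by Cst7 (4.78, SE 0.48), Clec7a (3.37, SE 0.35), Itgax (3.18, SE 0.31) and Ifnb1 (3.1, SE 0.36), followed by Rims1, a gene of the presynaptic release site (23.6 ± 14.6 CPM in APP females, 1.86 ± 1.69 in WT females; 2.91, SE 0.6, adjusted p = 0.0067). Of the 23 microglial genes 15 rose, and 20 did when adjusted over the list alone (median 0.93; adjusted p = 3.9e-23; adjusted p = 0.11 with an estimated correlation). The largest falls were Pttg1 (-2.52, SE 0.72), Lao1 (-2.41, SE 0.3), Map3k6 (-2.39, SE 0.46), Rpl21 (-2.18, SE 0.62) and B3gnt3 (-1.91, SE 0.5). Myelin genes were higher: 6 of 10 oligodendrocyte markers rose and 1 fell, or 9 and 1 when adjusted over the list alone (median 1.42; adjusted p = 1.8e-05; adjusted p = 0.65 with an estimated correlation). Cldn11 rose by 1.58 (SE 0.35), Aspa by 1.04 (SE 0.22) and Cnp by 0.7 (SE 0.16), and Mal fell by 0.67 (SE 0.13). Neuron markers rose with them in 3 of 10, and 6 rose and 1 fell when adjusted over the list alone (median 0.91; adjusted p = 0.0057; adjusted p = 0.67 with an estimated correlation): Snap25 by 1.74, Camk2a by 2.49 and Eno2 by 0.97. The astrocyte filament gene Gfap rose by 2.2. Mitochondrially encoded genes were higher in 13 of 13, with 0 called by limma and 12 when adjusted over the list alone (median 0.6; adjusted p = 6.6e-06; adjusted p = 0.67 with an estimated correlation). Glucocorticoid-responsive genes fell in 7 of 15, and in 10 when adjusted over the list alone (median -0.62; adjusted p = 5.3e-07; adjusted p = 0.11 with an estimated correlation). Tsc22d3, an anti-inflammatory target of the receptor, was at 278 ± 148 CPM in APP females and 647 ± 29.2 in WT females (-1.36, SE 0.27, adjusted p = 0.0052), and Angptl4 (-1.24, SE 0.25), Per1 (-0.89, SE 0.19) and Errfi1 (-0.61, SE 0.15) were lower too. With genotype shuffled, a camera p as small came in 1 of 100 splits for plaque-associated microglia, 2 for glucocorticoid response and 4 for oligodendrocyte markers. It came in 8 for neuron markers and 9 for mitochondrially encoded genes, so these lists were not beyond chance.

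In females 332 genes were higher and 405 lower. Of these 737 genes, 145 were also called between the name styles of the APP libraries, 142 with the same sign, against 71.8 expected of independent draws. With name style as a covariate 53 genes were higher and 29 lower. Within long library names, 2 APP against 6 WT females, 17 genes were higher and 0 lower, with 796 genes at an unadjusted p under 0.05 in limma. These 17 were also called in all females, with the same sign. They were Cst7 (5.55, SE 0.59), Clec7a (4.06, SE 0.43), Itgax (3.54, SE 0.4), Igf1 (3.39, SE 0.43), Ifnb1 (3.04, SE 0.47), Lilrb4a, Baiap2l2, Lpl, Spp1, Il1b, Egln3, Hpse, Pdcd1, Ifi207, Tlr2, Ank and Hif1a (0.71, SE 0.13). All 23 microglial genes were higher there (median 1), all 14 smooth muscle genes lower (median -0.63, list adjusted p = 9.7e-07, or 0.68 with an estimated correlation) and 14 of 15 glucocorticoid-responsive genes lower (median -0.36, list adjusted p = 4.9e-05, or 0.33). Oligodendrocyte markers had 7 of 10 higher (median 0.37, list adjusted p = 0.34) and neuron markers 5 of 10 (median 0.03, list adjusted p = 0.9); limma called 0 genes in these 4 lists. A fit of all 24 libraries with APP split by name style, run before the planned one, gave 23 higher and 3 lower, 25 of them shared with all females. Neither fit called Pttg1 (-0.07), B3gnt3 (-0.14), Rims1 (1.36), Lao1 (-1.74), Map3k6 (-1.45) or Rpl21 (-1.17).

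The counts in all females moved with single libraries. They were 189 higher and 263 lower without APP female replicate 3, 165 and 198 without replicate 4, 160 and 208 without replicate 5, and 156 and 213 without replicate 6. They were 178 and 201 without WT female replicate 2, 196 and 233 without replicate 5, and 148 and 190 without replicate 6. The call of Pttg1 ended when any of APP female replicates 3 to 6 or of the WT females was left out (adjusted p = 0.057 to 0.11). That of Rpl21 ended without APP female replicate 1 or any of 3 to 6, or any of WT female replicates 1 to 5 (0.06 to 0.098), and that of B3gnt3 without any of APP female replicates 3 to 6 or WT female replicates 2, 3, 5 or 6 (0.053 to 0.081).

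Whether the genotype difference itself differed between the sexes was tested as an interaction, with positive values where the difference was higher in females. Neuron and myelin transcripts led it. Kif5a (4.87, SE 1.05), Crym (4.79, SE 0.74), Camk2a (4.55, SE 1.04) and Kif5c (4.35, SE 0.91) were among the largest rises. Kif5a, on chromosome 10 (127225696 to 127263348), was at 576 ± 376 CPM in APP females and 90.8 ± 73 in WT females, but at 54.8 ± 81.6 in APP males and 182 ± 153 in WT males (SD, n = 6; adjusted p = 0.012). Of 10 oligodendrocyte markers 8 were higher, or 9 when adjusted over the list alone, among them Ermn (2.46, SE 0.52), Cldn11 (2.29, SE 0.5) and Mbp (3.72, SE 0.81). The list's median was 2.2 (adjusted p = 1.4e-06; adjusted p = 0.46 with an estimated correlation). Of 10 neuron markers 7 were higher, as when adjusted over the list alone, with Snap25 at 2.96 (SE 0.69), Eno2 at 1.55 (SE 0.37) and Map2 at 2.44 (SE 0.59); the median was 1.44 (adjusted p = 6.2e-05; adjusted p = 0.46 with an estimated correlation). Astrocyte markers were higher in 4 of 13, or 10 when adjusted over the list alone: Sox9 (1.86, SE 0.39), Gfap (2.21, SE 0.49), S100b (2.39, SE 0.65) and Slc1a2 (2.33, SE 0.68). The astrocyte median was 1.49 (adjusted p = 2.8e-05; adjusted p = 0.49 with an estimated correlation).

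The largest negative values belonged to Upk1b (-2.47, SE 0.66), Erdr1x (-1.8, SE 0.5), Hsf2bp (-1.76, SE 0.36), the cytochrome gene Cyp2e1 (-1.74, SE 0.49) and Rasd1 (-1.66, SE 0.46). The plaque-associated microglia list showed no interaction (1 of 23 higher, median -0.16, adjusted p = 0.68), nor did smooth muscle (median 0.19, adjusted p = 0.53). In all, 678 genes were higher and 291 lower, against 915 and 769 in DESeq2 and 595 and 456 in edgeR, so the balance rests on the scaling and test. Without the 4 short-named APP females 10 were higher and 5 lower, and without the 4 short-named APP males the balance turned to 385 higher and 854 lower. In the latter fit the males differ in name style as well as genotype. With name style as a covariate 588 were higher and 194 lower, and 387 of these 782 were among the 969. A genotype effect that itself differs with name style cannot be separated from the interaction, since WT males all had short names and WT females long ones. Single libraries moved the counts too: 400 were higher without APP male replicate 2, 540 lower without replicate 3, and 422 higher and 191 lower without replicate 4. The counts were 409 and 179 without APP female replicate 5, 358 and 162 without replicate 6, 382 and 176 without WT male replicate 4, 414 and 175 without WT female replicate 5, and 339 and 152 without replicate 6. Leaving out single libraries also ended the calls of Upk1b (APP male 4, adjusted p = 0.05), Erdr1x (APP male 4 and 6, APP female 1, WT male 1, 4 and 5, WT female 5 and 6, adjusted p = 0.05 to 0.066), Rasd1 (APP male 4, APP female 3, 5 and 6, WT male 1, WT female 5 and 6, adjusted p = 0.05 to 0.065) and Cyp2e1 (APP female 3, 4 and 6, WT male 5, WT female 2, 5 and 6, adjusted p = 0.05 to 0.06).

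**Figure D4:**
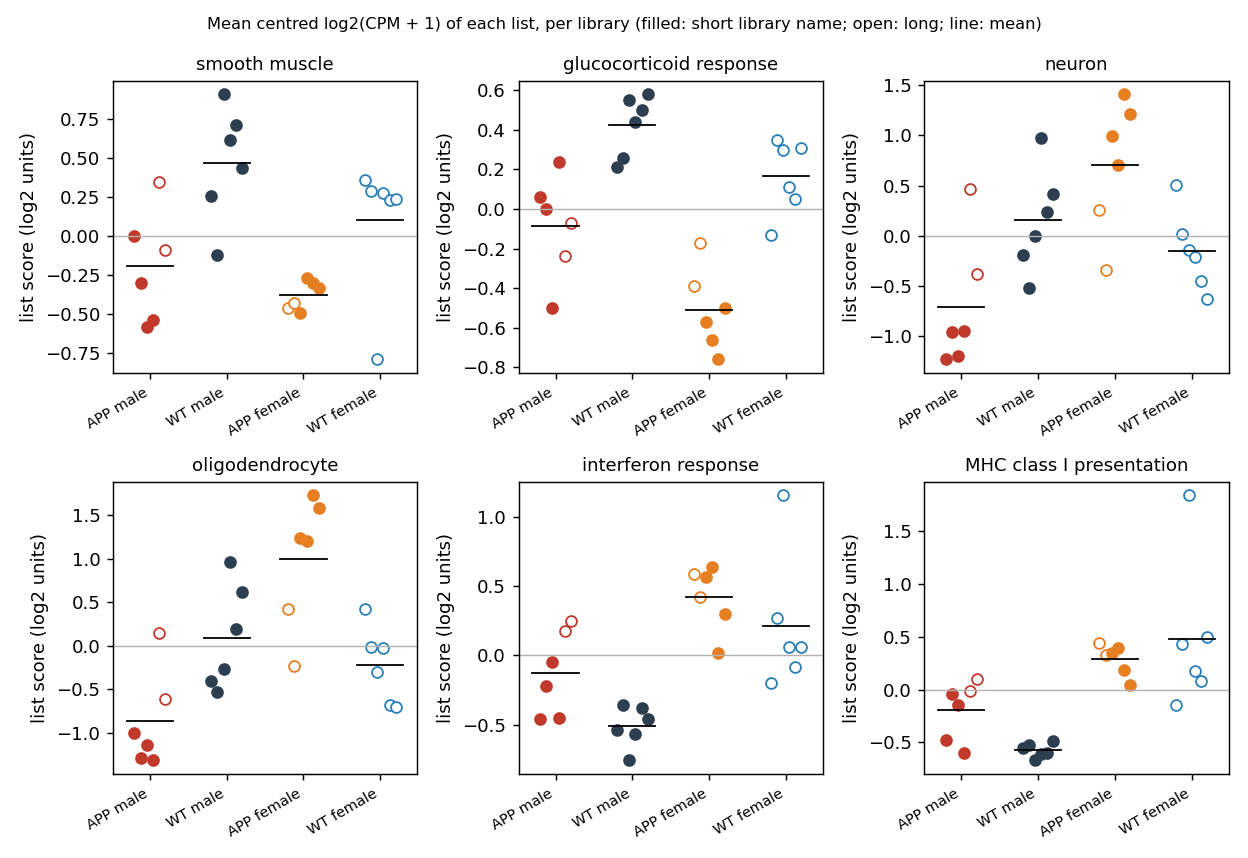
Score of 6 gene lists per library, the mean of centred log2(CPM + 1) over a list's genes in log2 units, for the 4 groups of 6 mice. Filled points are short-named libraries, open points long-named ones and lines group means; WT males lay at -0.76 to -0.36 for the interferon response and APP females at 0.02 to 0.64.

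Females were compared with males with the genotypes averaged. Beside Xist (8.22, SE 0.11) and the Y-linked genes Ddx3y (-7.34, SE 0.07), Eif2s3y (-6.66, SE 0.08), Kdm5d (-5.69, SE 0.06) and Uty (-5.11, SE 0.07), females had higher levels of interferon-inducible and antigen presentation genes. Of 25 interferon response genes 23 were higher, and 25 when adjusted over the list alone (median 0.6; adjusted p = 1.7e-15; adjusted p = 0.51 with an estimated correlation). Irf7, a regulator of interferon genes, was at 210 ± 46.2 CPM in APP females and 124 ± 25.4 in APP males, and at 167 ± 66.9 and 84 ± 10.1 in WT females and males (0.84, SE 0.13, adjusted p = 0.00037). Ifi27l2a (1.2, SE 0.2), Oasl2 (0.66, SE 0.12) and Ifit3 (0.9, SE 0.17) followed. Of 14 genes of antigen presentation by MHC class I, 13 were higher, and 14 when adjusted over the list alone (median 0.76; adjusted p = 5.2e-10; adjusted p = 0.51 with an estimated correlation): H2-K1 (0.82, SE 0.14), Psmb9 (1.02, SE 0.18), Nlrc5 (1.26, SE 0.24) and H2-Q4 (0.77, SE 0.16), where the H2 genes resemble each other and could share reads. The other large rises were Cyp2e1 (1.64, SE 0.24), the nucleic acid sensor gene Zbp1 (1.62, SE 0.32), the myelin gene Mobp (1.45, SE 0.39) and H2-Q6 (1.4, SE 0.35). Zbtb16, a transcription factor gene, was the largest fall outside the Y chromosome (-2.15, SE 0.28), at 216 ± 53.1 CPM in WT males and 68.8 ± 52, 21.5 ± 8.52 and 29.4 ± 15.6 in APP males, APP females and WT females.

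In this comparison 1358 genes were higher in females and 480 lower. RLE scaling gave 903 and 747, which moves the share of higher calls, and library-name style as a covariate 277 and 186. Of the 25 interferon response genes, 5 were called within APP (median 0.57) and 21 within WT (median 0.72), where WT female replicate 3 had the highest score of the list (1.16). The 14 genes of MHC class I presentation had a median of 0.49 within APP, with no gene called, and of 0.95 within WT, with 13 called, where WT female replicate 3 again had the highest score (1.84). Mobp was lower in females within WT (-0.29). Since WT males all had short names and WT females long ones, a sex difference within WT cannot be told from one of name style. Of the 1838 genes called, 203 were also called between the name styles of the APP libraries, against 179.1 expected of independent draws. Of these, 6 had the same sign for female minus male as for short-named minus long-named, and the others the opposite sign.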

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

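All tests of explanations here, the library-name fit, the clock score and the score of neuron and oligodendrocyte genes were chosen after the results were seen; the comparison within long library names and the tests for stray libraries and for interaction were planned.

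The first pattern is the parting of the APP libraries by the style of their names, with 1339 genes. A library or sequencing batch that goes with the style would put the WT males, all short-named, level with short-named APP, but over the 141 genes with a log2 difference of at least 1 their median place was 0.63 on a scale from long-named APP (0) to short-named APP (1), with quartiles of 0.39 and 0.83; WT females, all long-named, lay at 0.09 (quartiles -0.06 and 0.24), close to long-named APP as such a batch would put them. The genes were chosen by the gap between the same APP libraries that set this scale, which can pull other groups inward. The place of the WT males therefore does not settle whether a batch goes with the style. Depth is argued against by the 5 of 8 short-named APP libraries whose totals lay within the range of the long-named ones. A strain background that differs between mice could put differing genes side by side on chromosomes, and 11 neighbouring pairs were found among these genes against a median of 1 and at most 7 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). All 1339 genes held 177 pairs (median 127, at most 172, permutation p = 1e-04). Interaction calls with a log2 difference of at least 1, which are not independent of name style, held 22 (median 14, at most 33, permutation p = 0.027). The shuffles treat neighbouring genes as independent, so neighbours that share reads or change together could also give an excess. Background stays a hypothesis.

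The second pattern is the lower level of glucocorticoid-responsive genes in APP. With genotype shuffled, a camera p as small came in 5 of 100 splits averaged, 32 in males and 2 in females. In males the list was thus not beyond chance. With the clock score as a covariate the female median was -0.61 (6 fell) against -0.62 (7 fell) before, which argues against time of day as the whole cause in females. In males it went from -0.28 (median SE 0.2, 5 fell) to 0.06 (median SE 0.32, 1 fell), where the larger error keeps time of day open. In long-named females the median was -0.36 (median SE 0.28, 14 of 15 lower, 0 called by limma in this list; list adjusted p = 4.9e-05, or 0.33 with an estimated correlation). With name style as a covariate it was -0.53 (list adjusted p = 5.4e-10 at the preset correlation, with no estimated one computed). By these medians a background that goes with the name style is less able to hold the whole female difference but could hold part of it. The 2 long-named APP libraries cannot settle this. Genotype itself, as a biological explanation, stays open and was not tested apart from these.

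The third pattern is the lead of neuron and oligodendrocyte transcripts in the interaction. An effect of library-name style shared by the sexes is argued against by the score of both lists, which differed between short-named and long-named libraries by -1.04 in APP males (-1.17 to -1.11 against -0.5 and 0.31) and by 1.23 in APP females (0.96 to 1.57 against -0.29 and 0.34). With style as a covariate the list medians were 1.27 and 1.98 (camera adjusted p = 0.0049 and 0.00068 at the preset correlation, with no estimated one computed). A cause that marks the short-named APP females apart from the males was not tested and stays open, as without those females 10 genes were higher and 5 lower. Tissue RNA carried into the vessel preparation could raise these genes together: with the score of both lists as a covariate 49 calls remained outside the lists against 954 before, 36 of them shared. Mean scores of 2 other lists, in APP and WT females and then APP and WT males, went the same way. Choroid plexus and ependyma had 0.37, -0.15, -0.68 and 0.46 (SD 0.49 to 0.95). Oligodendrocyte precursors had 0.12, -0.05, -0.56 and 0.49 (SD 0.25 to 0.45). Homeostatic microglia, also cells of the tissue, went the other way, at -0.24, 0.05, 0.32 and -0.13 (SD 0.25 to 0.74). The median SE of all genes also rose from 0.155 to 0.203 with the covariate. Without the condition on that rise, set after the result was seen, the value would have counted for carry-over. Carry-over therefore stays open, as does a biological difference between the sexes, not tested apart from these.

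For the gene counts of all 5 comparisons 1 of 100 splits, the real one, gave as many genes. This argues against a random division of the libraries, except for the interaction. There the shuffling of genotype also removes the difference shared by the sexes, so the splits do not test the interaction alone. All splits ignore name style, which coincides with sex in WT and divides APP, so they do not part genotype or sex from it. The highest other split called 271 genes against 1663 with the sexes averaged, 1112 against 1966 in males, 0 against 737 in females (limma), 348 against 969 for the interaction and 60 against 1838 between the sexes. Chance was not excluded for the numbers of lists called. As many lists were called in 33 splits with the sexes averaged (17 real, highest other 25), 12 in males (24, 30), 69 in females (10, 21), 32 for the interaction (16, 32) and 27 between the sexes (17, 29).

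Of 384 groups of 6 values, of 95 named genes and of the library totals, 51 had a library far from the other 5. Chance gives about 1 in 20 for independent normal values. These were values on the linear scale, of genes that move together and some hardly detected, so the excess over that rate is no test. The following are CPM values of those libraries. WT female replicate 3 held 16: B3gnt3 at 62.7, Lcn2 at 191, Lmod1 at 12, Mylk at 140, Ifit2 at 102, Ifi44 at 64.4, Zbp1 at 156, H2-Q6 at 948, Irf7 at 298, Ifi27l2a at 32, Oasl2 at 299, Ifit3 at 222, H2-K1 at 4680, Psmb9 at 286, Nlrc5 at 372 and H2-Q4 at 1830, all above the other WT females but for Lmod1 and Mylk, which were below. APP male replicate 5 held 10, all above: Rpl21 at 35.8, Kif5a at 217, Rims1 at 8.05, Cldn11 at 4.78, Cnp at 46.6, Camk2a at 61.2, Kif5c at 27.3, Snap25 at 5.83, Map2 at 19.2 and Ermn at 2.03. WT male replicate 4 was above in 4: Cst7 at 8.91, Slc6a11 at 43.8, Slc1a2 at 886 and Slc4a4 at 31.8.

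WT female replicate 1 was above in Tfrc (286 CPM) and Dbp (46.5) and below in Cdkn1a (438). APP female replicate 2 was above in Rpl21 (32.5), Cdkn1a (652) and Errfi1 (75.2). WT male replicate 2 was above in Xist (1.41) and H2-Q6 (58.6) and below in Gfap (7.85). APP female replicate 4 was above in Kdm5d (0.196) and Eif2s3y (0.223), WT female replicate 2 in Mx1 (7) and Fkbp5 (111), and WT male replicate 5 in Itgax (5.25) and Eif2s3y (176). Single values were those of Crym in APP female replicate 5 (38), Zbtb16 in APP female replicate 6 (37.9), Upk1b in APP male replicate 3 (4.29, below), Isg15 in APP male replicate 4 (51.7, below), Ank in WT female replicate 5 (54.6, below) and Uty in WT female replicate 6 (0.117).

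For 31 of the 95 named genes the genotype difference differed between the sexes by the interaction test. In 22 it was higher in females, on the log2 scale: Crym 4.79, Kif5c 4.35, Kif5a 4.87, Camk2a 4.55, Rims1 3.99, Mbp 3.72, Mobp 3.47, Snap25 2.96, Ermn 2.46, Map2 2.44, S100b 2.39, Slc1a2 2.33, Cldn11 2.29, Dio2 2.22, Gfap 2.21, Sox9 1.86, Eno2 1.55, Aspa 1.25, Rgs5 1.18, Npas2 1.15, Cnp 0.85 and Prnp 0.64. In the others it was lower: Hsf2bp -1.76, Per3 -1, Nr1d2 -1.11, Upk1b -2.47, Rasd1 -1.66, Erdr1x -1.8, Cyp2e1 -1.74, Per1 -0.93 and Angptl4 -1.17.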

How the results depend on the processing

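The pseudocounts, TMM scaling, edgeR, the clock score, the fit of 6 groups and the settings that leave out APP libraries or keep 1 genotype were chosen after seeing the data; the others were planned. Over the named genes and called lists, 3241 gene values and 2306 list values kept direction and call, 182 and 368 lost the call, 24 and 0 gained it, and 1 and 20 changed direction. Pairs of counts are genes higher and lower, in the order averaged, males, females, interaction and sex; where a cause is not stated, the cause was not tested.

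RLE gave 903 and 747 for sex. A log2 minimum of 0.5 leaves fewer genes by construction: 215 and 292, 294 and 760, 172 lower in females, 153 lower for the interaction, 216 and 86. A threshold of 0.1 admits more: 990 higher averaged, 705 and 753, 1174 and 647, 781 lower for sex. With a correlation estimated per list 1 list was up and 0 down averaged, and 0 and 0 in the other comparisons. Fitting males alone gave 410 and 837. Name style as a covariate gave 53 and 29 in females and 277 and 186 for sex, with 7 lists down in females and 13 for the interaction. Correction for 2 surrogate variables gave 1235 and 1547, 1377 higher in males, 737 and 885, 1265 and 845, and 1237 lower for sex. Voom with quality weights gave 1339 and 1522, 1243 higher in males, 843 and 924, 1108 and 785, and 1165 lower for sex. DESeq2 gave 989 higher averaged, 1169 higher in males, 659 and 714, 769 lower for the interaction and 1062 lower for sex. EdgeR gave 456 lower for the interaction and 753 for sex.

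Within short names 2116 genes were lower in males, and within long names 17 were higher and 0 lower in females (796 at an unadjusted p under 0.05 in limma), with fewer libraries; the fit of 6 groups gave 23 and 3. Without APP males 1 to 4 the counts were 437 and 309 averaged, 256 lower in males, 385 and 854 for the interaction and 270 and 261 for sex, with 4 lists down for the interaction and 5 for sex. Name style then goes with genotype in males. Without APP females 3 to 6 they were 192 and 252 averaged, 17 and 0 in females, 10 and 5 for the interaction, and 3 lists down for sex. The clock score gave 123 and 66 averaged, 69 and 68 in males and 284 higher for the interaction. It went largely with genotype in males, so these counts do not part the clock from genotype. Sex within APP gave 635 and 196, and within WT 721 lower.

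Medians that changed direction without APP males 1 to 4 were TGF-beta and BMP (-0.03 averaged, -0.14 in males), immediate early genes (0.02 averaged, -0.07 in males, 0.04 interaction, 0 sex), clock (0.07 averaged, 0.13 in males, -0.08 interaction) and pericyte (0.05 in males); the test's direction changed where the median did not. With the clock score they were TGF-beta and BMP (-0.04, -0.14 in males), immediate early genes (-0.01) and clock (-0.15, -0.14 in males, 0.01 interaction), as a score of clock genes removes by construction. Between the sexes ribosomal proteins changed within APP (0), and Mobp (-0.29), homeostatic microglia (0.18), neuron (-0.35) and oligodendrocyte (-0.31) within WT.

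Leaving out each library in turn gave 503 to 785 higher and 787 to 1396 lower averaged, 514 to 893 and 828 to 1589 in males, 148 to 491 and 190 to 513 in females, 339 to 947 and 152 to 540 for the interaction, and 949 to 1865 and 356 to 588 for sex. Lists up and down ranged over 7 to 15 and 3 to 5, 13 to 17 and 7 to 10, 6 to 10 and 2 to 6, 8 to 9 and 6 to 14, and 4 to 10 and 5 to 8. The lowest lists up were without WT female replicate 1 averaged and without WT female replicate 3 for sex; APP male replicate 1 gave 5 there.

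The replicate block gave 715 and 1065, 794 and 1314, 352 and 412, 643 and 331, and 1458 and 572. The labels do not say that the numbers pair animals. Over 12 pairs of an APP and a WT library of 1 sex with the same number the correlation ran from -0.34 to 0.34. Of these, 1 was best matched with its own number, which gives no sign of pairing but cannot exclude it. A minimum of 1 CPM in 6 libraries removed 0 genes and tests nothing, since all deposited values already met it. No further filter was applied here. Depth limits low genes, for which 3 reads are 0.0395 to 0.0573 CPM.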

Other observations

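The counts of overlap between the sexes and the tests here on neighbouring genes and on genes that set a group apart were chosen after the results were seen; the gene list tests were planned.

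With the sexes averaged, 6 lists of endothelial genes were not called between the genotypes, though single members were. Of 15 genes of transcytosis and caveolae 5 fell, among them Cavin2 (-0.32), Cavin1 (-0.23), Cavin3 (-0.22) and Ap2m1 (-0.13), with 10 not called (list median -0.08, adjusted p = 0.067; limma). Of 15 endothelial markers 1 rose (median 0.05, adjusted p = 0.41), and of 15 junction genes 0 were called (median -0.03, adjusted p = 0.41; limma). Arterial markers (median 0.04, adjusted p = 0.98), venous markers (-0.03, adjusted p = 0.98) and capillary markers (0.12, adjusted p = 0.1) were not called either. Genes of MHC class II presentation rose in 3 of 8 (median 0.77, adjusted p = 0.013; adjusted p = 0.64 with an estimated correlation), and complement genes rose in 4 of 15 and fell in 1 (median 0.37, adjusted p = 0.0093; adjusted p = 0.49 with an estimated correlation). A camera p as small came in 30 and 22 of 100 splits with genotype shuffled within sex, so neither list was beyond chance.

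Across all genes, which are not independent replicates, the genotype differences of males and females had a Pearson r of 0.02 and a Spearman rho of 0.03. In both sexes 72 genes were higher in APP and 82 lower, and 31 were called with opposite signs. Independent draws would give 17 and 37.2, but genes move together and both APP groups held 4 short-named and 2 long-named libraries, so the excess is no test of genotype.

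The WT males were set apart from the other 18 libraries by 122 genes, against 2 for APP males, 23 for APP females and 23 for WT females, where chance gives 0.2. Those 122 genes held 3 neighbouring pairs against a median of 1 and at most 6 in shuffled positions (permutation p = 0.095), which leaves a background of their own undecided.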
